A study of Homo sapiens with 9 samples.

How the data were processed

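RNA was measured in 9 libraries of the HT-29 cell line: 3 of control cells, 3 of cells exposed to BP at 5 µg/mL and 3 exposed to CRA at 40 µg/mL, each after 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, 3 µg was used, and libraries were made with a KAPA kit for messenger RNA, a poly(A)-based preparation. The submitters' processing notes name CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 2.0.0 and DESeq2 1.26.0 and the build GRCh38, without order or role. The annotation release, the strand setting and the treatment of reads that match several places are not stated. Reads of near-identical copies and of overlapping or antisense genes are therefore uncertain.

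The authors deposited a table of read counts per gene, whole numbers that sum to between 13845143 and 17976246 per library, and these counts were used for every main result. They also deposited a table of TPM, used only as an alternative. In 11689 of 11689 genes with at least 20 counts in every library, the deposited TPM equalled the count divided by a fixed length per gene and scaled per library, to within 0.01 on the log2 scale. Columns were matched to groups by their names. The control columns carry a name that matches no other group. Of 58884 identifiers, 58611 were found in GENCODE release 29, which gave coordinates on GRCh38. Symbols are those of the deposited TPM table, which gives one for 56939 of the identifiers, and list members under another name were matched through a table of current and older gene names (1178 of 1179 entries found).

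Genes were kept with the filterByExpr function of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 15878. Counts were scaled with the trimmed mean of M-values. One model with a mean per group was fitted to all 9 libraries with the quasi-likelihood test of edgeR, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes came from the same fit. The replicate number was not used as a term. Levels are CPM, read counts divided by the scaled library size. Replicates of a group differed by more than sampling noise (chi-square per gene 1.65 to 2.53), and 0 pairs were identical. Each library was treated as a replicate, although these values do not show that they came from separate cultures. The p-value of a gene measures the spread between these libraries, while that of the camera test described below compares genes with other genes.

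Gene lists for pathways, cell types and RNA quality, 48 in number, were written before the data were examined, with the comparisons, tests, naming rule and alternatives. A list with at least 5 measured members was tested with camera from limma 3.58.1, which compares its genes with all others, at a preset correlation of 0.01. This left 47 lists, since the leukocyte and endothelial list had 3 measured genes. Camera was repeated with an estimated correlation. A member count gives genes past the threshold over all genes tested. No list member had a group with all libraries at 0 counts (0 of 965). Lists share members, such as NRF2 targets with genes against lipid peroxidation, and tests of such lists are not independent.

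Genes were named by a rule. A gene needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and all 3 libraries of one group beyond all 3 of the other. The 10 largest changes per direction were taken for each compound against control and 8 for CRA against BP, passing over features known only by a clone or locus name and genes of the Y chromosome and XIST. Up to 4 members of each list with the smallest p in a comparison were added, and their values may be given for the other comparisons. Results for some genes that the rule names are not reported here. For named genes with at most 20 counts in a group, the ratio of summed counts over library sizes is given with an exact 95% interval. Such intervals cover counting error only, since reads are not independent molecules.

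Shared controls were simulated 30 times by drawing all 9 libraries from the control means. The fits were tested on simulated data in which genes in sets of 50 had known changes and the proteasome list was shifted as a whole. For BP against control, CRA against control and CRA against BP, 49, 49 and 42 of 50 genes changed by 2 on the log2 scale were recovered, and those missed lay below 1 CPM. Of unchanged genes, 13 of 15646, 5 of 15646 and 12 of 15647 were called. Besides the shifted list, 1 of 46, 0 of 46 and 0 of 44 lists were called. The simulated genes were drawn independently of each other and few were changed. These rates therefore do not cover lists with correlated members or data in which most genes change. Alternatives were relative log expression and upper-quartile scaling, other low-count filters, fits of only the 2 groups compared, the replicate number as a block, a test against a fold change of 1.5, DESeq2 1.42.0, limma on log2 TPM with pseudocounts of 1 and 0.1, fry and an estimated correlation for lists, and leaving out each library. GC content and length were those of the longest transcript of a gene in the same GENCODE release. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.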

Results

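The series measured messenger RNA in HT-29, a human colorectal cancer cell line with a BRAF mutation that the labels describe as an enterocyte line of wild-type genotype. Its title concerns plant galactolipids and drug-resistant colorectal cancer. Cells were left as controls or exposed for 24 h to BP at 5 µg/mL or to CRA at 40 µg/mL, 3 libraries per group and 9 in all. BP and CRA are code names in the labels. What the control cells received in place of the compounds is not stated there. Total counts per library ranged from 13845143 to 17976246, with overlapping ranges in the 3 groups, and 15878 of 58884 listed genes had enough counts to be tested. The comparisons ask what each compound did to the transcriptome of these cells and how the compounds differed.

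Libraries of one group lay close together. The first principal component held 65.6% of the variance over 10575 genes and separated the BP libraries from the controls, with the CRA libraries between them, and the second, with 31.2%, separated the CRA libraries from both. The common biological coefficient of variation was 2.69%, so very small differences passed the test. Whether the 3 libraries of a group came from separate cultures is not stated, and the p-values of genes measure only the spread between these libraries. Those of camera compare the genes of a list with other genes and depend on the correlation assumed between them. Transcripts of the mitochondrial genome took 10.5% ± 0.371 of counts in the controls, 8.45% ± 0.233 with BP and 10.8% ± 0.154 with CRA (SD, n = 3). Long noncoding RNAs took 1.99% ± 0.0665, 1.52% ± 0.0464 and 1.54% ± 0.0270 of counts (SD, n = 3). Ribosomal RNA genes, those of the mitochondrial genome included, took 2.33% ± 0.0786, 2.502% ± 0.0347 and 1.56% ± 0.041 of counts (SD, n = 3).

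With BP, genes of the antioxidant, heat shock, endoplasmic reticulum stress and proteasome programmes were higher than in the controls, as were cell cycle genes. Immediate early, Wnt target and ATF4 target genes were lower. For cell cycle genes, not called between CRA and BP, a shift of the control libraries and an action of BP cannot be told apart. For immediate early and ATF4 target genes, such a shift may account for part of the decrease. The 10 genes with the most increased levels under the naming rule were *HSPA6*, *LUCAT1*, *AKR1B10*, *RBPMS2*, *OSGIN1*, *HMOX1*, *CYP4F11*, *ALDH3A1*, *GCKR* and *KBTBD8*. *HMOX1* (ENSG00000100292, GRCh38 chromosome 22, 35380361 to 35394214), which encodes the haem-degrading enzyme haem oxygenase 1, went from 6.73 ± 0.508 to 277 ± 9.79 CPM (read count normalised to library size, mean ± SD, n = 3). Its log2 fold change was 5.36 ± 0.059 (SE; adjusted p = 6.31e-64, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). *AKR1B10* (ENSG00000198074, chromosome 7, 134527592 to 134541408), an aldo-keto reductase of the NRF2 programme, rose from 17 ± 0.823 to 864 ± 9.13 CPM, or 50.8-fold (adjusted p = 1.07e-72). *OSGIN1*, an oxidative stress-induced growth inhibitor, rose 41.1-fold, and *CYP4F11*, a fatty acid hydroxylase, 30.5-fold. *HSPA6* (ENSG00000173110, chromosome 1, 161524540 to 161526910), a strictly stress-inducible member of the heat shock 70 kDa family, had 15 counts over the 3 control libraries and 2031 over the 3 BP libraries. Its ratio was 126-fold higher, with a 95% interval of 76.3 to 226 that covers counting error only, and its reads can be shared with the close paralogue *HSPA7*. *LUCAT1* (chromosome 5, 91054834 to 91314547), a long noncoding RNA annotated as antisense, rose from 2.96 ± 0.770 to 201 ± 8.09 CPM. Counting by strand is not stated, so reads of antisense genes cannot be told from those of overlapping genes. *ALDH3A1*, an aldehyde dehydrogenase, rose 20.98-fold and *GCKR*, the glucokinase regulator, 19.7-fold. *RBPMS2* and *KBTBD8* had 5 and 16 counts in the controls and were 51.6-fold (95% interval 21.8 to 160) and 19.5-fold (11.8 to 34.5) higher.

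Among the lists fixed before the data were examined, NRF2 antioxidant response genes rose with BP: 29 of 30 measured members were higher and 1 lower, with a median log2 fold change of 1.62 (camera, adjusted p = 6.29e-17). *TXNRD1*, which encodes thioredoxin reductase 1, rose from 424 ± 6.17 to 2994 ± 13.9 CPM, and *GCLM*, the modifier subunit of the enzyme that begins glutathione synthesis, from 84.8 ± 2.204 to 771 ± 7.04 CPM. Genes that protect from lipid peroxidation, a list that shares members with the former, held 14 higher and 6 lower of 22 (median 0.40, adjusted p = 0.0121; adjusted p = 0.245 with an estimated correlation). *FTL*, the ferritin light chain, rose 3.88-fold and *GCLC* 4.25-fold. Of 20 heat shock genes 18 rose and 1 fell (median 1.18, adjusted p = 1.04e-12). The co-chaperones *DNAJB4* and *BAG3* rose 11.8-fold and 7.08-fold, and *HSPH1* went from 722 ± 12.1 to 2802 ± 42.3 CPM. *HSPA1B* rose 4.65-fold, with reads that can be shared with its near-identical copy *HSPA1A*. Each of the 32 proteasome subunits was higher (median 1.195, adjusted p = 1.56e-18), among them *PSMD1* (4.15-fold), *PSMD3* (3.55-fold) and *PSMD2* (3.04-fold). Targets of ATF6 and XBP1 in the endoplasmic reticulum were higher in 22 and lower in 3 of 25 (median 1.09, adjusted p = 5.21e-11). *HSPA5*, which encodes the main chaperone of that compartment, rose from 622 ± 21.8 to 2148 ± 23.6 CPM, *DNAJB9* 7.67-fold and *DNAJC3* 3.57-fold. Lysosome and autophagy genes held 23 higher and 7 lower of 31 (median 0.58, adjusted p = 9.3e-05; adjusted p = 0.0696 with an estimated correlation). In that list *GLA*, a lysosomal galactosidase, rose 9.41-fold and the autophagy receptor *SQSTM1* 3.02-fold.

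Genes of G2 and M phase were higher with BP in 30 of 30 (median 1.77, adjusted p = 5.54e-20), S phase genes in 29 of 30 (median 1.30, adjusted p = 5.09e-13), and genes of homologous recombination and damage signalling in 22 of 24, with 2 lower (median 1.25, adjusted p = 1.6e-07). The proliferation marker *MKI67* went from 229 ± 12.1 to 1583 ± 36.4 CPM, *TOP2A* rose 3.48-fold, the ribonucleotide reductase subunit *RRM2* 7.80-fold and *BRCA2* 3.87-fold. Sterol synthesis genes were higher in 21 of 26 (median 0.78, adjusted p = 2.76e-07; adjusted p = 0.0633 with an estimated correlation), with *HMGCS1* up 2.96-fold. Glycolysis genes rose in 18 of 20 (median 0.71, adjusted p = 2.94e-05; adjusted p = 0.0936 with an estimated correlation), while the glucose transporter *SLC2A1* fell 2.07-fold. Nuclear-encoded subunits of the respiratory chain rose in 42 of 51 (median 0.40, adjusted p = 3.19e-06; adjusted p = 0.0875 with an estimated correlation), and protein-coding genes of the mitochondrial genome fell in 10 of 13 (median -0.38, adjusted p = 0.000305; adjusted p = 0.348 with an estimated correlation).

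The 10 genes with the most decreased levels in BP were *XAF1*, *IFI44L*, *G0S2*, *TNFSF15*, *TULP2*, *RARRES2*, *FOSB*, *GPX8*, *KNDC1* and *SLC6A9*. *IFI44L* (ENSG00000137959, chromosome 1, 78619922 to 78646145), an interferon-stimulated gene, went from 64.8 ± 3.17 to 0.737 ± 0.463 CPM. *G0S2*, a lipolysis inhibitor, fell 60.7-fold, the cytokine gene *TNFSF15* 44.1-fold, *GPX8* 27.2-fold and the glycine transporter *SLC6A9* 26.4-fold. *FOSB* (chromosome 19, 45467995 to 45475179), an immediate early transcription factor, fell from 1490 ± 63.0 to 53.5 ± 4.01 CPM (adjusted p = 1.66e-69). Of the sparsely counted genes, *XAF1* was 123-fold lower (95% interval 41.9 to 602, 3 counts in BP), *TULP2* 46-fold (20.8 to 127), *RARRES2* 31.4-fold (17.8 to 61.4) and *KNDC1* 28-fold (15 to 59.1). Interferon-stimulated genes were lower in 38 of 39 (median -2.04, adjusted p = 1.29e-14; adjusted p = 0.0633 with an estimated correlation), including *OAS3* (6.82-fold lower) and *PARP9* (8.60-fold lower). Antigen presentation genes fell in 13 of 14 (median -0.74, adjusted p = 0.00041; adjusted p = 0.122 with an estimated correlation), with *TAP2* down 2.25-fold. NF-kB targets fell in 13 and rose in 3 of 20 (median -0.76, adjusted p = 0.0144; adjusted p = 0.143 with an estimated correlation), and *LCN2* was 3.17-fold lower.

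Immediate early genes were lower with BP in 20 of 22 (median -1.89, adjusted p = 6.46e-14). *FOS* went from 697 ± 15.4 to 89.9 ± 5.20 CPM and *JUNB* fell 7.27-fold. Genes induced by ERK signalling fell in 14 and rose in 4 of 20 (median -0.89, adjusted p = 0.000267): *CCND1*, which encodes cyclin D1, was 3.20-fold lower, and *FOSL1* was 2.95-fold higher. Wnt targets and crypt stem cell genes fell in 16 of 18 (median -1.44, adjusted p = 2.37e-06), with *SOX9* down 4.68-fold and *ZNRF3* 3.53-fold. ATF4 targets of the integrated stress response fell in 26 and rose in 4 of 33 (median -1.05, adjusted p = 7.81e-10). The serine synthesis genes *PSAT1* and *PHGDH* fell 5.77-fold and 6.97-fold, and *PCK2* fell 6.18-fold. Cytosolic tRNA synthetases fell in 13 of 18 (median -0.62, adjusted p = 0.000101; adjusted p = 0.115 with an estimated correlation). Ribosomal protein genes fell in 74 of 78 by a small amount (median -0.44, adjusted p = 1.68e-21; adjusted p = 0.148 with an estimated correlation), and ribosome biogenesis genes in 18 of 27 (median -0.37, adjusted p = 0.00033; adjusted p = 0.0816 with an estimated correlation). *MYC* itself was 2.08-fold lower. Goblet and secretory cell genes fell in 13 of 15 (median -1.69, adjusted p = 3.68e-05): *AGR2* was 3.03-fold lower and the mucin gene *MUC5AC* 3.22-fold. Receptor tyrosine kinase genes fell in 12 of 18 (median -0.48, adjusted p = 0.00466; adjusted p = 0.11 with an estimated correlation), epithelial junction genes in 15 of 22 (median -0.36, adjusted p = 0.000699; adjusted p = 0.122 with an estimated correlation), and TGF-beta and YAP targets in 14 of 18 (median -0.92, adjusted p = 0.00033; adjusted p = 0.0696 with an estimated correlation). *ERBB3*, *TJP3* and *AJUBA* were 2.73-fold, 4.67-fold and 11.9-fold lower.

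Over all genes, 5994 were higher and 6065 lower with BP than in the controls, or 75.9% of those tested. At least 2-fold changes were fitted for 1688 of the higher and 2868 of the lower genes, and at least 4-fold changes for 357 and 1002. Tested against a fold change of 1.5, 2536 were higher and 3348 lower. All 3 libraries of one group lay beyond all 3 of the other for 76.7% of genes, where chance gives 10%. Of 47 lists tested, 29 were called, 13 higher and 16 lower, and 12 of these calls held with an estimated correlation between genes. Adjusted over the list alone, the counts of members called were the same in 44 lists and differed by 1 gene in 3.

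**Figure D1:**
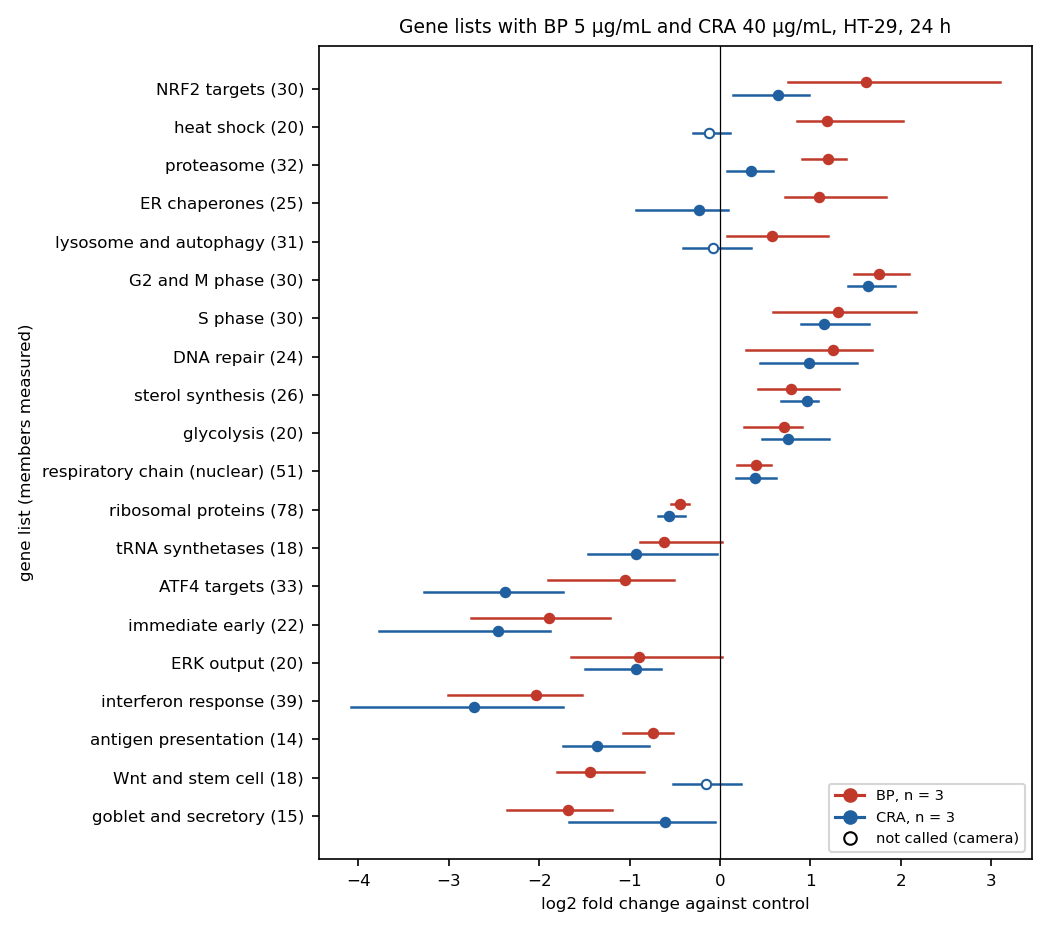
Median log2 fold change against control (point) and the range from the 25th to the 75th percentile of members (bar) for 20 of the gene lists, with BP (red) and CRA (blue), 3 libraries per group; open points mark lists that camera did not call. Heat shock genes had a median of 1.18 with BP and -0.12 with CRA, while G2 and M phase genes had 1.77 and 1.64.

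With CRA, ATF4 target, immediate early, ERK output and interferon-stimulated genes were lower than in the controls. Cell cycle, sterol synthesis and glycolysis genes were higher. For interferon, ERK output, cell cycle and sterol synthesis genes, camera called no difference between CRA and BP. A shift of the control libraries and an action of CRA cannot be told apart for them. For ATF4 target and immediate early genes, such a shift may account for part of the decrease. Among the 10 genes with the most increased levels were *ALDH3A1*, *BCYRN1*, *AKR1B10*, *RDM1*, *CDKN2C*, *DMBX1*, *UGT1A6*, *CLDN2* and *PFKFB4*. *ALDH3A1* (chromosome 17, 19737984 to 19748943) rose from 1.27 ± 0.435 to 39.3 ± 1.57 CPM (log2 fold change 4.96 ± 0.12, SE; adjusted p = 2.1e-43), and *AKR1B10* to 199 ± 3.63 CPM, or 11.7-fold. *UGT1A6*, which shares exons with the other UGT1A genes, rose 8.58-fold. The cyclin-dependent kinase inhibitor gene *CDKN2C* rose 8.85-fold, the claudin gene *CLDN2* 8.08-fold, *PFKFB4*, a regulator of glycolysis, 7.57-fold, *RDM1* 9.14-fold and *DMBX1* 8.83-fold. *BCYRN1*, whose sequence resembles Alu repeats so that its reads are hard to place, was 12.97-fold higher.

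The 10 most decreased genes with CRA were *IFI44L*, *XAF1*, *LAMP3*, *FOSB*, *OAS2*, *SAMD9L*, *EPSTI1*, *ATF3*, *TULP2* and *IFI6*. *IFI44L* was 414-fold lower, with 8 counts over the CRA libraries (95% interval 210 to 960). *OAS2* (chromosome 12, 112978395 to 113011723) went from 56.5 ± 1.38 to 0.694 ± 0.285 CPM and *IFI6* (chromosome 1, 27666061 to 27672218) from 86.3 ± 2.79 to 1.90 ± 0.636 CPM. *LAMP3* was 95.2-fold (51.5 to 199), *SAMD9L* 88.3-fold (34.1 to 326), *EPSTI1* 65.3-fold (29.7 to 179), *XAF1* 135-fold (45.7 to 656) and *TULP2* 50.1-fold (22.7 to 138) lower. *ATF3* (ENSG00000162772, chromosome 1, 212565334 to 212620777), a stress-induced transcription factor, fell from 203 ± 2.85 to 4.08 ± 0.836 CPM (log2 fold change -5.64 ± 0.072, adjusted p = 5.43e-60), and *FOSB* to 18.1 ± 2.40 CPM. Each of the 39 measured interferon-stimulated genes was lower (median -2.72, adjusted p = 1.33e-20), among them *IFI27* (21.2-fold). Antigen presentation genes fell in 13 of 14 (median -1.36, adjusted p = 1.12e-06; adjusted p = 0.0582 with an estimated correlation), with *HLA-B* down 7.41-fold and *HLA-C* 3.47-fold. Reads of these polymorphic genes can be shared or lost where an allele differs from the reference. NF-kB targets fell in 18 of 20 (median -0.87, adjusted p = 5.05e-05), with *LCN2* 3.91-fold lower.

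ATF4 targets were lower with CRA in 32 of 33 (median -2.38, adjusted p = 1.27e-27). *SLC7A11*, the cystine transporter, went from 934 ± 15.2 to 146 ± 3.44 CPM, *PSAT1* fell 8.86-fold and the amino acid transporter *SLC38A2* 5.48-fold. Cytosolic tRNA synthetases fell in 13 of 18 (median -0.93, adjusted p = 4.5e-07; adjusted p = 0.0582 with an estimated correlation). Immediate early genes were lower in 22 of 22 (median -2.45, adjusted p = 1.41e-21) and genes induced by ERK signalling in 20 of 20 (median -0.93, adjusted p = 1.27e-12). *EGR1* fell from 1167 ± 13.1 to 96.0 ± 1.24 CPM and *DUSP5*, an ERK phosphatase, 7.49-fold. Receptor tyrosine kinase and ligand genes fell in 11 of 18 (median -0.37, adjusted p = 0.000348; adjusted p = 0.0582 with an estimated correlation), with *HBEGF* down 15.7-fold, and TGF-beta and YAP targets in 13 of 18 (median -0.68, adjusted p = 0.000255; adjusted p = 0.0582 with an estimated correlation). Goblet and secretory genes fell in 10 of 15 (median -0.60, adjusted p = 0.000809), led by *KLF4* at 14.2-fold, and enterocyte genes in 14 of 19 (median -0.80, adjusted p = 0.0137; adjusted p = 0.0617 with an estimated correlation), with *DPP4* down 4.25-fold. Ribosomal protein genes fell in 74 of 78 (median -0.56, adjusted p = 1.51e-32, and 0.0949 with an estimated correlation). Ribosome biogenesis genes fell in 14 and rose in 6 of 27 (median -0.23, adjusted p = 0.0322). Their adjusted p was 0.21 with an estimated correlation and 0.0586 in a fit of CRA and control alone, from 2.16e-06 to 0.21 over the alternatives.

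Cell cycle genes were higher with CRA in 30 of 30 for G2 and M phase (median 1.64, adjusted p = 1.3e-28), in 30 of 30 for S phase (median 1.15, adjusted p = 2.52e-21) and in 22 of 24 for DNA repair (median 0.99, adjusted p = 2.64e-11). *MKI67* reached 1316 ± 47.6 CPM, and *RRM2* rose 6.45-fold. Sterol synthesis genes rose in 22 of 26 (median 0.97, adjusted p = 5.62e-11), with *ACAT2* up 4.43-fold. Glycolysis genes rose in 17 of 20 (median 0.76, adjusted p = 2.15e-11), with *LDHA* up 2.44-fold and *PGAM1* 2.83-fold, and respiratory chain subunits in 42 of 51 (median 0.39, adjusted p = 2.45e-10). NRF2 targets rose in 23 and fell in 5 of 30 (median 0.64, adjusted p = 4.5e-07). *AKR1C2*, whose reads can be shared with its paralogues, rose 7.37-fold, and *SLC7A11*, also an ATF4 target, fell 6.404-fold. Proteasome subunits rose in 24 of 32 (median 0.34, adjusted p = 1.81e-06; adjusted p = 0.171 with an estimated correlation). Endoplasmic reticulum chaperone genes fell in 16 and rose in 6 of 25 (median -0.24, adjusted p = 0.00252; adjusted p = 0.183 with an estimated correlation), with *HERPUD1* down 5.63-fold and *XBP1* 3.96-fold. Heat shock genes were not called as a list (6 higher, 11 lower of 20, median -0.12, adjusted p = 0.242), nor were Wnt targets (2 higher, 9 lower of 18, median -0.16, adjusted p = 0.0751).

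Over all genes, 4920 were higher and 5541 lower with CRA than in the controls, or 65.9% of those tested. At least 2-fold changes were fitted for 1047 and 1525 genes and at least 4-fold changes for 155 and 417. Tested against a fold change of 1.5, 1430 were higher and 1863 lower. The groups did not overlap for 68.4% of genes, where chance gives 10%. Of 47 lists 29 were called, 12 higher and 17 lower, and 14 calls held with an estimated correlation. Counts adjusted over the list alone were the same in 42 lists and differed by 1 gene in 5.

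**Figure D2:**
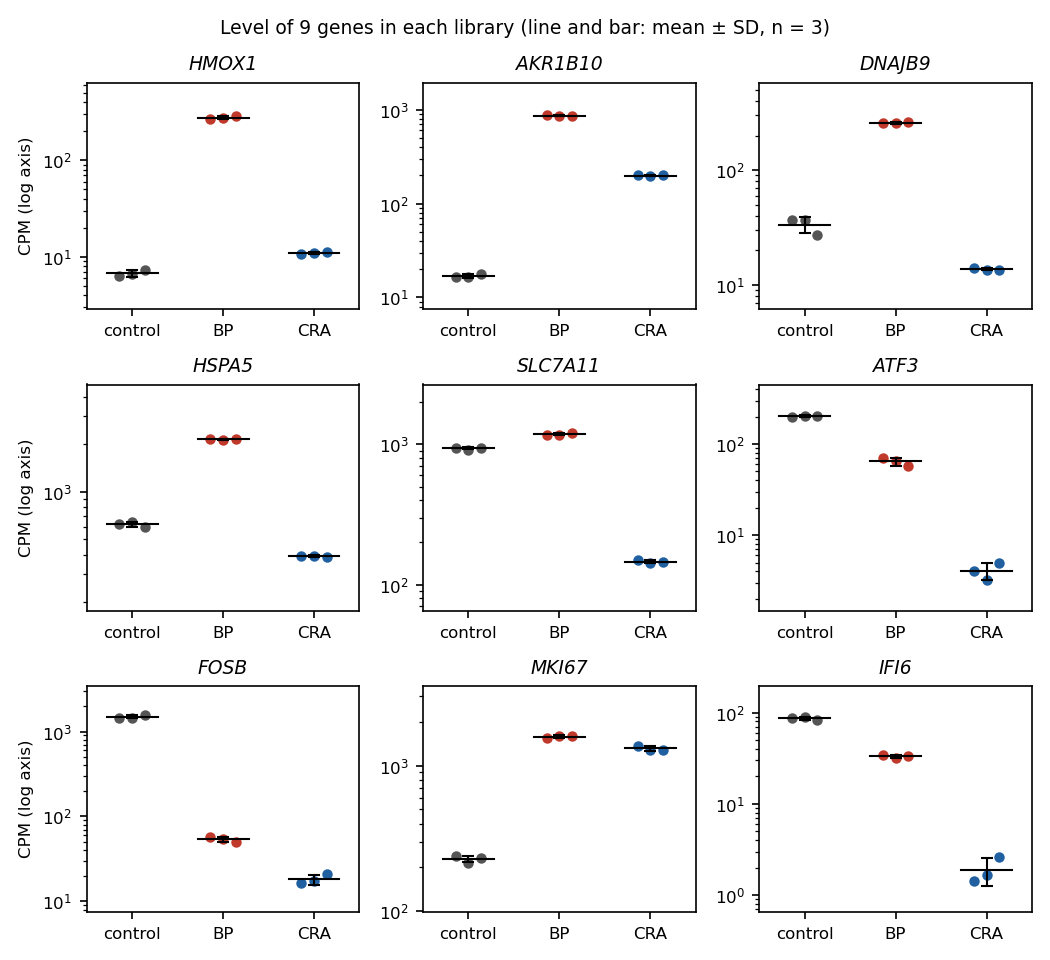
Level of 9 genes in each library in CPM on a log axis, with controls in grey, BP 5 µg/mL in red and CRA 40 µg/mL in blue; each point is 1 library and lines with bars show the mean ± SD of 3 libraries. *DNAJB9* stood at 33.5 CPM in the controls, 257 with BP and 13.7 with CRA, while *MKI67* rose from 229 to 1583 and 1316 CPM.

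Set against each other, CRA and BP differed in endoplasmic reticulum chaperone, NRF2 target and Wnt target genes, among other lists. The doses differed, 40 µg/mL for CRA and 5 µg/mL for BP, so these values compare single doses and not the compounds at a matched dose. Genes lower with CRA than with BP were led by *HSPA6*, *RBPMS2*, *LUCAT1*, *HMOX1*, *CHAC1*, *MIR22HG*, *SLC7A11-AS1* and *DNAJB9*. *HMOX1* stood at 10.9 ± 0.289 CPM with CRA against 277 ± 9.79 with BP (log2 fold change -4.66 ± 0.052, adjusted p = 2.35e-63). *CHAC1* (chromosome 15, 40952962 to 40956519), a glutathione-degrading enzyme under ATF4, stood at 1.71 ± 0.184 against 43.0 ± 2.26 CPM, and *DNAJB9* (ENSG00000128590, chromosome 7, 108569568 to 108574850) at 13.7 ± 0.292 against 257 ± 3.28 CPM. *LUCAT1* was 26.9-fold, *MIR22HG* 22.7-fold and *SLC7A11-AS1*, named as antisense to *SLC7A11*, 19.9-fold lower. Reads of *SLC7A11-AS1* cannot be told from those of overlapping genes, since counting by strand is not stated. *HSPA6* was 116-fold (95% interval 74.4 to 194) and *RBPMS2* 37.7-fold (18.9 to 88.2) lower. The endoplasmic reticulum chaperone list was lower in 25 of 25 (median -1.35, adjusted p = 4.22e-21) and NRF2 targets in 27 of 30 (median -0.93, adjusted p = 2.98e-17), both also called with an estimated correlation. *HSPA5* was 5.49-fold, *HERPUD1* 12.1-fold, *GCLM* 8.03-fold and *SLC7A11* 8.10-fold lower with CRA. Proteasome subunits were lower in 32 of 32 (median -0.88, adjusted p = 4.41e-18; adjusted p = 0.0661 with an estimated correlation) and heat shock genes in 19 of 20 (median -1.40, adjusted p = 8.88e-16; adjusted p = 0.0538 with an estimated correlation). ATF4 targets were lower in 24 and higher in 6 of 33 (median -0.93, adjusted p = 3.35e-09; adjusted p = 0.0538 with an estimated correlation). In that list *PPP1R15A* and *SESN2* stood at 37.4 ± 3.51 and 9.87 ± 0.276 CPM with CRA against 375 ± 23.1 and 85.0 ± 4.57 with BP. Immediate early genes were lower in 15 and higher in 4 of 22 (median -1.06, adjusted p = 0.000352; adjusted p = 0.0538 with an estimated correlation), and lysosome and autophagy genes lower in 26 of 31 (median -0.56, adjusted p = 3.82e-07; adjusted p = 0.055 with an estimated correlation).

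Genes higher with CRA than with BP were led by *MIR210HG*, *KLHDC7A*, *PRR15L*, *COLCA1*, *RBBP8NL*, *CD200*, *AKAP7* and *SLITRK6*. *SLITRK6* (chromosome 13, 85792787 to 85806683), a neuronal transmembrane protein gene, stood at 159.5 ± 3.87 CPM in the controls, 7.43 ± 1.003 with BP and 117 ± 6.34 with CRA. *COLCA1*, annotated as antisense, was 19.6-fold higher with CRA than with BP, *PRR15L* 19.96-fold, *KLHDC7A* 21.1-fold, *RBBP8NL* 16.6-fold, the membrane glycoprotein gene *CD200* 16.5-fold and *AKAP7* 16.5-fold. These differences lay mainly in decreases with BP. Against the controls, log2 fold changes with BP and CRA were -3.99 and 0.31 for *COLCA1*, -3.99 and 0.33 for *PRR15L* and -3.31 and 0.73 for *AKAP7*. They were -4.43 and -0.03 for *KLHDC7A*, -4.32 and -0.27 for *RBBP8NL* and -3.81 and 0.24 for *CD200*, with no call of these with CRA. *MIR210HG*, the host gene of a hypoxia-induced microRNA, had 462 counts with CRA and 17 with BP, a ratio of 24.9-fold (95% interval 15.4 to 43.2). Wnt targets and crypt stem cell genes were higher with CRA than with BP in 16 of 18 (median 1.01, adjusted p = 3.66e-07), also with an estimated correlation. In that list *SOX9* stood at 172 ± 3.77 against 57.2 ± 1.92 CPM. The medians of the list against the controls were -1.44 with BP and -0.16 with CRA. Epithelial junction genes were higher in 14 of 22 (median 0.16, adjusted p = 0.00207; adjusted p = 0.279 with an estimated correlation), glycolysis genes in 15 of 20 (median 0.25, adjusted p = 0.00047; adjusted p = 0.279 with an estimated correlation), ribosome biogenesis genes in 15 of 27 (median 0.23, adjusted p = 0.0125; adjusted p = 0.292 with an estimated correlation) and genes of the mitochondrial genome in 11 of 13 (median 0.57, adjusted p = 7.41e-08; adjusted p = 0.292 with an estimated correlation). The G2 and M phase and interferon lists were not called (medians -0.060 and -0.48, adjusted p = 0.364 and 0.139), although 23 interferon genes were lower and 7 higher with CRA, and upper-quartile scaling turned the former median to 0.053. Ribosomal protein genes were called lower at a median of -0.080 (adjusted p = 0.00533; adjusted p = 0.671 with an estimated correlation), and upper-quartile scaling turned that median to 0.033 and ended the call.

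Over all genes, 5605 were higher and 5517 lower with CRA than with BP, or 70.0% of those tested, with at least 2-fold changes in 1905 and 1304 and at least 4-fold changes in 492 and 265. Tested against a fold change of 1.5, 2236 were higher and 1965 lower. The groups did not overlap for 71.7% of genes, where chance gives 10%. Of 47 lists 17 were called, 5 higher and 12 lower, and 3 calls held with an estimated correlation. Counts adjusted over the list alone were the same in 41 lists and differed by 1 gene in 6.

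The effects of the compounds against the controls overlapped. Genes higher with both numbered 3298 and genes lower with both 3644, together 6942, and 1791 genes changed in opposite directions. Independent lists of these sizes would share 1857 higher and 2117 lower genes. Across genes, which are not independent replicates, the fold changes correlated at 0.607, against an average of 0.520 in 30 simulations of unchanged groups that shared the same controls, and 69.7% had the same sign, against 67.3%. In those simulations every fold change is noise, so sharing the controls alone sets the correlation and the share of equal signs. These simulated values are therefore no reference for data in which most genes change. The covariance of the fold changes, which keeps their size, was 0.604 against 0.0161 in the simulations, a difference of 0.588. The covariance was 1.18 with no low-count filter and 0.339 on log2(TPM + 1). The simulations cover noise from sharing the controls and not a systematic shift of the control group, which a single control group leaves open. Among genes changed the same way by both were *MKI67*, *FOSB*, *IFI44L* and *AKR1B10*. *HSPA5* (log2 fold change 1.79 with BP and -0.67 with CRA), *DNAJB9* (2.94 and -1.29) and *FOSL1* (1.56 and -1.99) changed in opposite directions.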

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

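Opposite changes against the controls, with the difference between the compounds itself tested, drew attention to 1 gene list and 7 of the named genes. The test of a shift of the control libraries was chosen only after the list values had been seen. The tests of bias, pseudogenes, dose and other splits of the libraries were set out before their values.

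Endoplasmic reticulum chaperone genes were higher than control with BP (median 1.09) and lower with CRA (-0.24, a call lost at adjusted p = 0.183 with an estimated correlation), and differed by a median of -1.35 between CRA and BP. A trend of fold change on GC content, length and mean abundance, fitted on genes outside the list, was removed. The median then stood at 0.996 with BP, where 22 of 25 members kept the sign, and at -1.20 between CRA and BP, where 25 of 25 did, which argues against such a bias as the whole cause there. The smaller decrease with CRA stood at -0.23 after removal, but only 16 of 25 members kept the sign, so that part cannot be told apart from members that go both ways. With 1 dose of each compound, a difference of dose and one of compound cannot be told apart either, and a response to BP that CRA lacks may remain a hypothesis.

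*SLC7A11-AS1* differed by -4.32 on the log2 scale between CRA and BP, with 2.096 and -2.22 against the controls. Counting by strand is not stated, so its reads cannot be told from those of overlapping genes. *SLC7A11* itself lay at 916 to 943 CPM in the control libraries, 1164 to 1210 with BP and 143 to 150 with CRA. *DNAJB9* differed by -4.23 (2.94 and -1.29) and *MIR22HG* by -4.50 (2.66 and -1.84). The opposite order held for *MIR210HG*, where the fitted difference of 4.61 rests on 17 counts with BP and 462 with CRA, a ratio of 24.9-fold (95% interval 15.4 to 43.2). It stood at 1.97 ± 0.810 CPM in the controls, 0.363 ± 0.246 with BP and 8.999 ± 0.580 with CRA. *AKAP7* differed by 4.05 (-3.31 and 0.73), *COLCA1* by 4.30 (-3.99 and 0.31) and *PRR15L* by 4.32 (-3.99 and 0.33).

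Several lists moved the same way with both compounds (the interferon list with BP at adjusted p = 0.0633 with an estimated correlation), as would follow if the 3 control libraries alone stood apart, for instance in growth state. That account requires CRA and BP to be alike. ATF4 targets differed between them by a median of -0.93 and immediate early genes by -1.06. Camera called both at the preset correlation but not with an estimated one (adjusted p = 0.0538 each). A shift of the controls alone would leave no such difference, but this test was chosen after the values were seen. A shift of the controls together with an action of 1 compound would leave one as well. How much of the decrease with BP or with CRA comes from the controls is therefore not settled. G2 and M phase genes differed by -0.060, which upper-quartile scaling turned to 0.053, and interferon genes by -0.48. Neither list was called, although 23 interferon genes were lower and 7 higher with CRA. S phase (median 0.054), DNA repair (0.0125), sterol synthesis (0.13), respiratory chain (-0.013) and ERK output genes (-0.068) were not called between CRA and BP either, with members going both ways. For these lists a shift of the controls and an action shared by the compounds cannot be told apart with a single control group. Removing the trend on GC content, length and abundance left medians with BP and CRA of -1.22 and -2.44 for ATF4 targets, -1.98 and -2.48 for immediate early genes, 1.53 and 1.71 for G2 and M phase and -1.96 and -2.72 for interferon genes, which argues against such a bias.

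Ribosomal protein genes were lower than control with BP and CRA by small medians (-0.44 and -0.56), calls lost at adjusted p = 0.148 and 0.0949 with an estimated correlation. These genes are short and abundant, but after the trend was removed the medians were -0.71 and -0.57, with 78 and 77 of 78 members below 0, so the trend does not account for them. Reads moved to processed pseudogenes would raise those. The summed level of 939 ribosomal protein pseudogenes instead fell from 311 ± 10.6 CPM to 247 ± 0.820 with BP and 238 ± 11.3 with CRA (SD, n = 3), a gain of -0.324% and -0.318% of what the parent genes lost. The parent genes summed to 68874 CPM in the controls, 49139 with BP and 46009 with CRA. Beside these totals the pseudogenes are so small that a rise to match the loss was unlikely in advance, and the test carries little weight. The treatment of reads that match several places is not stated, and reads dropped from parents and pseudogenes alike would not show here. The list differed between CRA and BP by a median of -0.080, which upper-quartile scaling turned to 0.033, so a shift of the control libraries or a shared action of the compounds may remain.

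For the counts of changed genes, 3 libraries against 3 give 10 splits, too few for a share under 0.05. The real split, 1 of the 10 with a count as large as its own, gave 12059 genes for BP against control, 10461 for CRA against control and 11122 for CRA against BP, and the highest of the other splits gave 0 in each. For gene lists, where 1 of 10 splits also reached the real count, the real splits gave 29, 29 and 17 and the highest other 25, 18 and 13. Every other split leaves more libraries of one group on one side, so it retains part of the real difference. For genes changed in the same direction by BP and CRA, 1 of 100 groupings of the 9 libraries, the real one, reached 6942, and the highest other reached 5442. Groupings that mix the real groups put their difference into the spread within a grouping, so that most gave 0, and this comparison says little beyond the closeness of libraries of one group.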

How the results depend on the processing

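Every setting reported here was planned before the data were examined. Across 21 alternatives no call of the main settings among 571 results for named genes and leading list members and 141 list results reversed its tested direction. The gene results were chosen in these same libraries by large change or small p, so kept calls were likely in advance. They do not show how the other called genes would fare. Of the gene results, 566 were called, and over the alternatives a call was kept 10683 times, lost 70 times and gained 1 time, and 94 stayed without one, with 63 of the losses under the test against a fold change of 1.5, 3 with DESeq2 and 4 without 1 of the libraries. Of the list results 75 were called, and a call was kept 1146 times, lost 54 times and gained 69 times in the same direction, and 981 stayed without one. In 6 further list results without a call by camera, fry made a call in the direction opposite to that of camera. With BP these were genes that favour lipid peroxidation (median -0.013, fry adjusted p = 0.00567, higher), fatty acid synthesis (0.175, 0.00562, lower), glycerolipid (0.053, 0.0242, higher) and eicosanoid genes (-0.244, 3.06e-05, higher). With CRA they were genes that protect from lipid peroxidation (median 0.167, fry adjusted p = 0.000312, lower) and HIF targets (-0.084, 0.00127, lower). The cause was not tested. Losses came mainly with an estimated correlation and gains with fry, which asks only whether the genes of a list move one way on balance and does not compare them with other genes.

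Testing against a fold change of 1.5, a stricter question, gave 2536 higher and 3348 lower genes for BP against control, 1430 and 1863 for CRA against control, 2236 and 1965 for CRA against BP, and 2121 genes changed in the same direction by both. With an estimated correlation 12, 14 and 3 lists were called for the 3 comparisons, and with fry 47, 45 and 42. Leaving out each library in turn gave 5871 to 6110 higher and 5935 to 6190 lower genes for BP against control, 4697 to 5008 and 5263 to 5636 for CRA against control, and 5361 to 5713 and 5325 to 5631 for CRA against BP. The lists called ranged from 29 to 29, 27 to 31 and 17 to 18, and genes changed in the same direction from 6613 to 6906. The correlation of fold changes ranged from 0.596 to 0.617 and their covariance from 0.630 to 0.657. The covariance of 0.604 with all 9 libraries lay below each of these values, and the low-count filter was applied anew in each fit. The correlation was 0.544 with no low-count filter, 0.640 in separate fits of 6 libraries and 0.549 with DESeq2. The covariance was 1.18 with no filter, 0.567 with at least 1 CPM in 3 libraries, 0.593 in separate fits, 0.904 with DESeq2, 0.339 on log2(TPM + 1) and 0.544 on log2(TPM + 0.1). The cause of these moves was not tested. DESeq2 gave no adjusted p for 11290, 12618 and 11954 of 34254 genes, and these stay out of the counts.

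Upper-quartile scaling moved the median log2 fold change of all genes to -0.106 for BP against control and 0.127 for CRA against BP, from -0.015 and 0.014. The share of changed genes that were higher moved from 49.7% to 44.1% and from 50.4% to 59.7%. It turned the median of the ribosomal protein list between CRA and BP from -0.080 to 0.033 and ended that call (adjusted p = 0.927, from 0.000868 to 0.927 over the alternatives). The sign of the medians of the G2 and M phase, ERK output, respiratory chain, receptor tyrosine kinase and p53 lists in that comparison also turned, as did that of the glycerolipid list for BP against control, and none of these lists was called.

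No pairing of libraries across groups by the numbers 1 to 3 was detected: deviations of libraries with the same number correlated at -0.0505 to 0.094, 0 of 9 pairs above 0.1, against -0.0953 to 0.070 for other pairs. Whether equal numbers mark a shared culture or day is not stated. With the number as a block, 5983 genes were higher and 6047 lower for BP against control, 4907 and 5508 for CRA against control, and 5597 and 5495 for CRA against BP. The lists called under the block numbered 29, 28 and 17, and the call of the replication histone list with CRA was the 1 lost (adjusted p = 0.052, from 1.2e-05 to 0.204 over the alternatives).

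Depth limits genes with few counts. In simulated data for CRA against BP, 42 of 50 genes changed by 2 on the log2 scale were recovered, and 40 of 40 at 1 CPM or more, while 22 of 50 changed by 0.25 were. Lists were not planned for the settings with no filter, a fold change of 1.5, DESeq2 or TPM.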

Other observations

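Lists not described above held further changes. With BP, p53 targets went both ways, 12 higher and 9 lower of 24 (median 0.11, mean -0.034, camera adjusted p = 0.653), and with CRA 8 were higher and 10 lower (adjusted p = 0.174). *CDKN1A*, the cyclin-dependent kinase inhibitor p21, stood at 32.3 ± 1.24 CPM in the controls, 82.8 ± 3.37 with BP and 7.98 ± 0.799 with CRA, and *MDM2* at 74.9 ± 2.38, 127 ± 1.24 and 74.99 ± 0.882 CPM. Genes of the BCL2 family, caspases and death receptors were not called (17 higher and 7 lower of 30 with BP, 10 and 15 with CRA; adjusted p = 0.177 and 0.242), and the BH3-only gene *PMAIP1* was 7.80-fold lower with CRA. Drug efflux and fluoropyrimidine genes were called higher with CRA (11 higher and 5 lower of 20, median 0.38, mean 0.077, adjusted p = 0.0182, and 0.101 with an estimated correlation). They were not called with BP (12 higher and 6 lower, adjusted p = 0.24) or in the direct comparison of CRA with BP (median 0.21, mean -0.13, adjusted p = 0.313). The efflux pump gene *ABCC2* stood at 1.02 ± 0.281, 11.1 ± 0.255 and 0.946 ± 0.267 CPM in controls, BP and CRA, and *TYMS*, the target of fluorouracil, at 20.9 ± 2.72, 47.3 ± 5.18 and 58.2 ± 1.62 CPM. Xenobiotic genes were called higher with CRA (10 higher and 4 lower of 15, median 0.60, adjusted p = 0.0322). Their adjusted p was 0.109 with an estimated correlation and 0.0516 in a fit of CRA and control alone, from 1.56e-06 to 0.109 over the alternatives. With BP they were not called, and median and mean differed in sign (-0.11 and 0.60, adjusted p = 0.542). Between CRA and BP the xenobiotic list was not called (median 0.091, adjusted p = 0.669). Genes that favour lipid peroxidation were not called against the controls, where medians of -0.013 with BP and 0.069 with CRA stood beside means of 0.17 and -0.32 (adjusted p = 0.932 and 0.737). Protective genes were not called with CRA against the controls (adjusted p = 0.48). Against BP they were called lower with CRA, with 13 lower and 8 higher of 22 (median -0.28, adjusted p = 0.0123, and 0.363 with an estimated correlation). Iron handling genes were called lower with CRA than with BP (9 lower and 3 higher of 15, median -0.31, adjusted p = 0.0336, and 0.36 with an estimated correlation). They were not called against the controls (adjusted p = 0.408 and 0.48). The tRNA synthetase list was also lower with CRA than with BP (14 of 18, median -0.25, adjusted p = 0.00169; adjusted p = 0.292 with an estimated correlation).

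Among lipid lists, liver X receptor targets were lower with BP (6 of 9, median -0.60, adjusted p = 0.00343; adjusted p = 0.0696 with an estimated correlation) and with CRA (7, median -1.34, adjusted p = 0.00431; adjusted p = 0.0582 with an estimated correlation), with the cholesterol exporter *ABCG1* at 38.0 ± 1.81, 6.69 ± 0.873 and 4.30 ± 0.156 CPM in controls, BP and CRA. PPAR targets and fatty acid oxidation genes were called higher with CRA (14 higher and 5 lower of 27, median 0.22, adjusted p = 0.0467, and 0.101 with an estimated correlation). That call ended without control replicate 2 or control replicate 3 (adjusted p = 0.0505 and 0.0514, from 1.01e-06 to 0.101 over the alternatives). The list was not called with BP (adjusted p = 0.411) or between CRA and BP (adjusted p = 0.296). Fatty acid synthesis, glycerolipid and eicosanoid genes were not called with BP (adjusted p = 0.796, 0.998 and 0.806) or CRA (0.205, 0.309 and 0.905). Median and mean of the fatty acid synthesis list differed in sign with BP (0.17 and -0.048), and the test pointed against the median for glycerolipid genes with BP (0.053) and eicosanoid genes with CRA (-0.12). HIF targets outside glycolysis were not called either (adjusted p = 0.249 and 0.864): *CA9* stood at 12.2 ± 0.600, 19.1 ± 1.60 and 44.0 ± 1.91 CPM in controls, BP and CRA, and *VEGFA* at 660.1 ± 10.5, 129 ± 1.002 and 112 ± 1.82 CPM. With CRA the test of this list pointed against its median (-0.084). Between CRA and BP its median was 0.47 (adjusted p = 0.0507), and it was called without control replicate 2 or 3, BP replicate 1 or 3, or CRA replicate 2 or 3 (from 3.14e-05 to 0.425 over the alternatives). Actin and SRF genes were called higher with CRA (12 higher and 4 lower of 17, median 0.31, adjusted p = 0.00169, and 0.185 with an estimated correlation). They were not called with BP (median 0.30, adjusted p = 0.428). Between CRA and BP this list was not called (median 0.092, adjusted p = 0.0944), and upper-quartile scaling called it (adjusted p = 0.0155, from 0.000151 to 0.463 over the alternatives). Metallothioneins, with 5 measured, were not called (adjusted p = 0.254 and 0.48).

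Markers of other cell types and of RNA quality gave the following values. Mesenchymal genes (6 measured) and enteroendocrine genes (5) were not called with BP (adjusted p = 0.735 and 0.287) or CRA (0.48 and 0.464), and enterocyte genes were not called with BP (adjusted p = 0.319) or between CRA and BP (adjusted p = 0.364). The leukocyte and endothelial list had 3 measured genes, too few for the test, and each is given here outside the naming rule. *CD14* stood at 3.26 ± 0.337 CPM in the controls, 1.11 ± 0.227 with BP and 2.63 ± 0.373 with CRA (SD, n = 3). *PECAM1* stood at 0.354 ± 0.232, 2 ± 0.333 and 1.33 ± 0.278 CPM, and *LYZ*, which gut epithelium also expresses, at 847 ± 28.6, 831 ± 18.6 and 913 ± 11.9 CPM. Epithelial junction genes were not called with CRA (adjusted p = 0.151), and neither was the lysosome list (adjusted p = 0.397) or that of the mitochondrial genome (median 0.26, adjusted p = 0.0513). The last list was called with CRA without control replicate 2, BP replicate 1, 2 or 3, or CRA replicate 1 or 3. It was also called with upper-quartile scaling (adjusted p = 0.0398) and in a fit of CRA and control alone (adjusted p = 0.0256), and adjusted p ranged from 0.013 to 0.574 over the alternatives. A fixed list of long noncoding RNAs, which holds host genes of small nucleolar RNAs beside nuclear-retained transcripts, was called lower with CRA (7 of 8, median -0.59, adjusted p = 0.000392), and not with BP (5 lower, adjusted p = 0.307) or between CRA and BP (adjusted p = 0.209). In that list the host genes *GAS5* and *SNHG1* fell 3.98-fold and 1.56-fold with CRA, and the nuclear-retained *MALAT1* fell 2.02-fold. Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, were called lower with CRA than in the controls (11 of 18, median -0.97, adjusted p = 0.0489; adjusted p = 0.204 with an estimated correlation) and than with BP (13, median -1.38, adjusted p = 0.00851; adjusted p = 0.271 with an estimated correlation). The former call ended without control replicate 3 (adjusted p = 0.0551) or CRA replicate 2 (adjusted p = 0.0708), within 1.2e-05 to 0.204 over the alternatives. Common reference genes were called higher with BP (12 of 15, median 0.27, adjusted p = 0.00269; adjusted p = 0.23 with an estimated correlation) and not with CRA (adjusted p = 0.0609), where the call was reached without CRA replicate 3 (adjusted p = 0.049, from 8.49e-05 to 0.421 over the alternatives). Between CRA and BP they were not called (median 0.016, mean -0.14, adjusted p = 0.864). Among these *ACTB* rose 1.85-fold with BP and 2.18-fold with CRA.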
